A study of Mus musculus with 12 samples.

How the data were processed

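The series held 12 Affymetrix mouse expression arrays, each hybridised with RNA of 1 sample of PGCLCs or PGCs. Per the labels' protocols, cells were sorted by their fluorescent reporters, a column kit yielded the RNA, cDNA equal to 5 ng of RNA (500 cells) was amplified by PCR with 12 initial cycles, and biotin-labelled cRNA was hybridised. Amplification from so little RNA can raise the spread of dim genes and can set them to very low values. The deposited table gave 1 log2 expression value per probe set and array, for 45101 probe sets. That the values are on a log2 scale was read from their range, with array maxima of 13.76 to 13.93; the log base, the summarisation of probes and the normalization before deposit were not given in the sources used here. Between 2.07% and 2.3% of the probe sets of an array stood at exactly 0.

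Group and replicate number came from the sample titles, which call the arrays biological replicates. Each of 6 groups had 2 arrays, and no per-sample column was left without a sample. Array medians ranged from 4.73 to 4.87 and 75th percentiles from 7.48 to 7.73. Because the medians differed by more than 0.1, the values were quantile normalized between arrays with limma, as a rule fixed before the data were examined required. Probe sets were named through the annotation table of the platform: 34958 had 1 gene, 932 had several and 9211 had none there, and 34754 of those with 1 gene were matched to the reference gene table by gene ID. Probe sets with several genes or none were left out. Each of 18194 genes was represented by the probe set with the highest mean over all arrays, and a gene was tested where at least 2 arrays exceeded 4.81, the median of all values, which left 13436 genes, 444 of them on the X chromosome. Tsix was not analysed here.

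Changes were tested with limma (version 3.58.1 in R 4.3.3) on 1 mean per group over all 12 arrays, so that the groups share 1 estimate of the spread with 6 residual degrees of freedom, followed by eBayes. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The 8 comparisons were d6 female minus d3, d3ag6 minus d3, d3ag6 minus d6 female, d3ag6 minus E12.5, d6 female minus E9.5, d6 female minus d6 male, d6 male minus E9.5, and E12.5 minus E9.5. An interaction contrast tested whether the change from d6 female to d3ag6 differed from that between E9.5 and E12.5. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

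The comparisons, tests, gene lists, naming rule and most of the other settings were chosen before the data were examined. The 23 lists were PGC specification, gonadal germ cell, meiosis, oocyte genes, pluripotency, primed epiblast, somatic mesoderm, BMP, WNT and retinoic acid response, hypoxia and glycolysis, cholesterol synthesis, cell cycle, cell cycle inhibitors, DNA methylation machinery, imprinted genes, immediate early and stress, X-linked widely expressed genes, Y-linked genes, and markers of gonadal somatic cells, mesenchyme, endothelium, blood and macrophages, neural cells, and gut and visceral endoderm. Some genes are in more than 1 list. Lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01 between genes, and again with an estimated correlation, and p-values were adjusted over all 184 tests of lists in comparisons. Beside each list stands the number of members called over all genes tested and the number called when p-values were adjusted over the list alone. X-linked genes as a group were compared with the other genes by camera, adjusted over the 8 comparisons.

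The genes named were the 8 with the largest change in each direction in d6 female minus d3, d3ag6 minus d6 female, d3ag6 minus E12.5, d6 female minus E9.5 and d6 female minus d6 male, and the 3 largest in each direction in the other comparisons. They were taken among called genes for which both arrays of a group lay above both arrays of the other, leaving out provisional symbols. To these came 2 to 4 members of each list in order of adjusted p, and always Xist, Ddx4, Dazl, Sycp3, Stra8, Prdm1 and Dppa3. The text prints a part of these genes and prefers those that kept their call with each array left out, a preference that was made after the values were seen. Some symbols of the lists matched no gene of the arrays and were not tested.

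The steps were tested on simulated data for d6 female minus d3, with 200 of 13436 genes changed: limma recovered 41% of 2-fold and 88% of 4-fold changes, and 5.8% of the genes called had not been changed. The other settings were no filter, a filter at the 75th percentile, the values as deposited, the mean of all probe sets of a gene, the replicate number as a block, eBayes with a trend and robust, only the arrays of the groups compared, a call that also needs a 2-fold change, and leaving out each array in turn; a group then left with 1 array is assumed to vary like the other groups. A fit of the 8 arrays coded EA1013 alone, and the array code as a block for d6 male minus E9.5, were added after the data were seen, as was a camera test of each of the 19 autosomes against the other autosomes, adjusted over 152 tests.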

Results

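Gene expression was measured in mouse germ cells that were either made in culture or taken from embryos. Primordial germ cell-like cells (PGCLCs) are induced from embryonic stem cells and stand in for primordial germ cells (PGCs), the embryonic precursors of oocytes and sperm. The 12 single-sample arrays fell into 6 groups of 2: female PGCLCs at day 3 (d3), female PGCLCs at day 6 (d6 female), female d3 PGCLCs kept for 6 more days in an aggregate with gonadal somatic cells of female E12.5 embryos (d3ag6), male PGCLCs at day 6 (d6 male), PGCs of female embryos at E12.5, and PGCs at E9.5, whose sex the labels give as unknown. PGCLCs carried the reporters Blimp1-mVenus (gene Prdm1) and stella-ECFP (Dppa3), and PGCs stella-EGFP. All cells were sorted on reporter fluorescence, which may even out Prdm1 in PGCLCs and Dppa3 in all groups. Values were log2 signal, given as the mean ± SD of a group (n = 2), and changes were differences of log2 means from limma with their standard error (SE). The p-values measured the spread between samples that the labels call biological replicates, and the number of arrays limited the precision.

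The arrays of d3, d6 female, d3ag6 and E12.5 carried the array code EA1013, while those of E9.5 and d6 male carried EA0831 or EA0842. Code and group could therefore not be told apart in the comparisons of d6 female with E9.5, d6 female with d6 male, and E12.5 with E9.5. In the 8 comparisons, genes named as changed kept their call with each array left out in turn unless an array is named beside them. No detection calls were used here, so the size of a change from or to a mean below 4.81, the median of all values, is imprecise. Of the 98 largest changes named over the comparisons, 82 had a group mean below that level, and 74 of these were still at least 2-fold when values below the level were set to it.

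**Figure D1:**
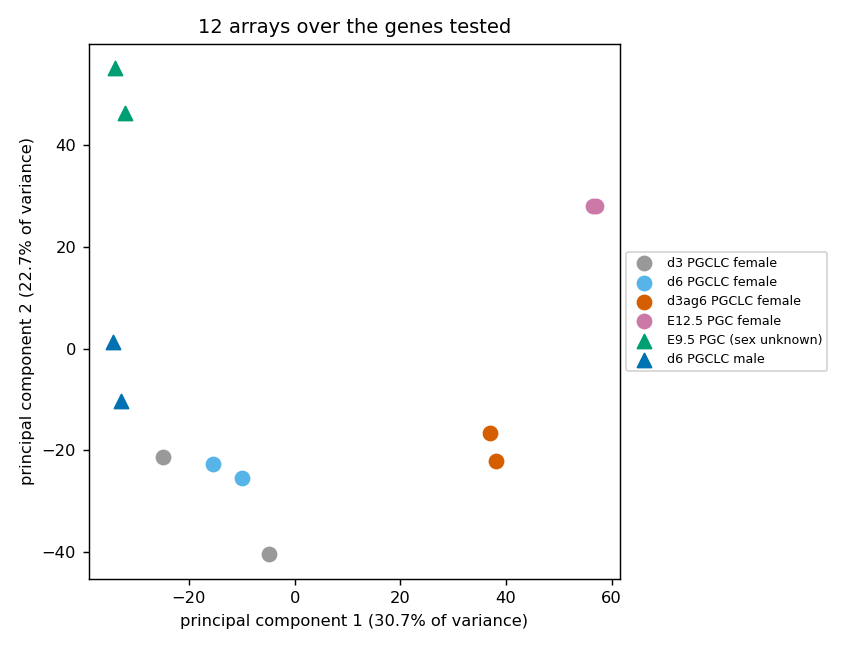
Principal component scores of the 12 arrays, with PC1 (30.7% of variance) on the x axis and PC2 (22.7%) on the y axis, coloured by group; circles are arrays coded EA1013 and triangles arrays coded EA0831 or EA0842. Each group is shown by its 2 arrays.

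The first comparison asked what 3 more days of culture did to female PGCLCs. Psmb8, a subunit of the immunoproteasome, fell from 9.36 ± 0.35 at d3 to 3.75 ± 0.66 at d6, a change of -5.61 (SE 0.39, adjusted p = 0.000521). Krt8, a keratin of simple epithelia, fell from 10.37 ± 0.40 to 6.13 ± 0.15 (-4.24, SE 0.44, adjusted p = 0.00245), and Krt18, its usual partner, fell by 2.39. Among the genes that rose were Khdc1a, from 3.54 ± 0.64 to 8.58 ± 0.98 (5.05, SE 0.50, adjusted p = 0.00197), Cpeb2, a protein that binds cytoplasmic polyadenylation elements (3.30, SE 0.43), and Nlrp4c (3.01, SE 0.28). The germ cell genes Ddx4 (0.47, adjusted p = 0.498), Dazl (1.92, adjusted p = 0.14), Sycp3 (0.32, adjusted p = 0.608) and Stra8 (-0.63, adjusted p = 0.453) did not pass the test, nor did Prdm1 (0.43, adjusted p = 0.503), Dppa3 (0.43, adjusted p = 0.147) or Xist (-0.47, adjusted p = 0.477).

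Of the 28 genes of the gonadal germ cell list, 9 rose and 19 did not pass over all genes tested, and 14 rose adjusted over the list alone. The list was higher at d6 (median change 0.835, camera adjusted p = 7.08e-09; adjusted p = 0.132 with an estimated correlation). The somatic mesoderm list was lower: of 30 genes, 9 fell, 1 rose and 20 did not pass, with 11 lower and 1 higher adjusted over the list alone (median -0.674, adjusted p = 1.48e-06; adjusted p = 0.0817 with an estimated correlation). Its members included the homeobox genes Msx1 (-2.87, SE 0.19), Hoxd9 (-3.43, SE 0.27) and Evx1 (-2.30, SE 0.26). The primed epiblast list was also lower, with 4 of 13 genes down and 9 not called, and 5 lower adjusted over the list alone (median -0.917, adjusted p = 3.23e-06; adjusted p = 0.123 with an estimated correlation). Sox3, a transcription factor of the epiblast and nervous system, changed by -3.51 (SE 0.38) and Sfrp2, a secreted WNT modulator, by -2.01 (SE 0.23).

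Of the 19 genes of the PGC specification list, 2 rose and 17 did not pass, and 6 rose adjusted over the list alone (median 0.259, adjusted p = 0.00261; adjusted p = 0.228 with an estimated correlation). Markers of endothelium were higher too, with 1 of 13 called, the angiopoietin receptor Tek (1.91, SE 0.34), and 4 adjusted over the list alone (median 0.693, adjusted p = 0.00109; adjusted p = 0.383 with an estimated correlation). Tek lost its call without d3 replicate 1 (adjusted p = 0.0644), d6 female replicate 1 (adjusted p = 0.131) or d6 female replicate 2 (adjusted p = 0.0628). Without d6 female replicate 1 the endothelial mean went from 0.84 to 0.493 and the call held (adjusted p = 0.0311). The BMP, WNT and retinoic acid response list was lower, with 4 genes down, 1 up and 16 not called, and 6 lower and 1 higher adjusted over the list alone (median -0.28, adjusted p = 0.0273; adjusted p = 0.241 with an estimated correlation). That call was lost without d3 replicate 2 (adjusted p = 0.224) or d6 female replicate 2 (adjusted p = 0.0542). Hypoxia and glycolysis genes were higher (2 of 28 up, 26 not called, and 2 up adjusted over the list alone; median 0.257, adjusted p = 0.00564; adjusted p = 0.519 with an estimated correlation). This last call was lost without d3 replicate 2 (adjusted p = 0.0781) or d6 female replicate 2 (adjusted p = 0.271), and its mean went from 0.356 to 0.536 without d6 female replicate 1. With the stricter filter, at the 75th percentile, the calls of endothelial markers (adjusted p = 0.108) and of the BMP list (adjusted p = 0.0546) were lost.

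Over all genes, limma called 545 genes between d3 and d6 female PGCLCs, 231 higher and 314 lower at d6, of which 424 changed at least 2-fold. Leaving out d3 replicate 1 or either d6 female array lowered the count. Without d3 replicate 2 the balance turned, with 281 higher and 180 lower.

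Cells aggregated with gonadal somatic cells were compared with cells in culture alone by setting d3ag6 against d6 female PGCLCs, both of which began as d3 cells. The groups also differ in time, 6 days after d3 against 3, so that aggregation and time cannot be told apart here. Stra8, the retinoic acid-responsive gene needed for entry into meiosis, rose from 3.65 ± 0.23 to 10.45 ± 0.30 (6.80, SE 0.36, adjusted p = 0.000108). Sycp3, a component of the synaptonemal complex, rose by 3.05 (SE 0.25, adjusted p = 0.000619), and Ddx4, an RNA helicase of germ cells, by 2.51 (SE 0.29, adjusted p = 0.00245). Dazl, an RNA-binding protein of germ cells, rose by 2.93 (SE 0.61, adjusted p = 0.0262). It lost its call without any 1 of the 4 arrays compared (adjusted p = 0.096 to 0.136), and without the filter on dim genes (adjusted p = 0.0571). Prdm1 (-0.30, adjusted p = 0.567), Dppa3 (0.12, adjusted p = 0.666) and Xist (-0.03, adjusted p = 0.968) did not pass.

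Of 30 meiosis genes, 16 rose and 14 did not pass over all genes tested, and 20 rose adjusted over the list alone (median 1.237, camera adjusted p = 3.37e-13; adjusted p = 0.12 with an estimated correlation). Tex12 and Syce1, both of the central element of the synaptonemal complex, rose by 3.12 (SE 0.27) and 2.21 (SE 0.21). Of the 28 gonadal germ cell genes, 13 rose and 15 did not pass, and 18 rose adjusted over the list alone (median 1.197, adjusted p = 1.73e-12; adjusted p = 0.0962 with an estimated correlation). They included Slc25a31, an ADP/ATP carrier of germ cells (2.64, SE 0.26) and Stk31 (1.91, SE 0.20). Of 12 oocyte genes, 2 rose and 10 did not pass, with 4 higher and 1 lower adjusted over the list alone (median 0.239, adjusted p = 0.196), and Sohlh2, a transcription factor of early oocytes, rose by 2.99 (SE 0.26, adjusted p = 0.000745).

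**Figure D2:**
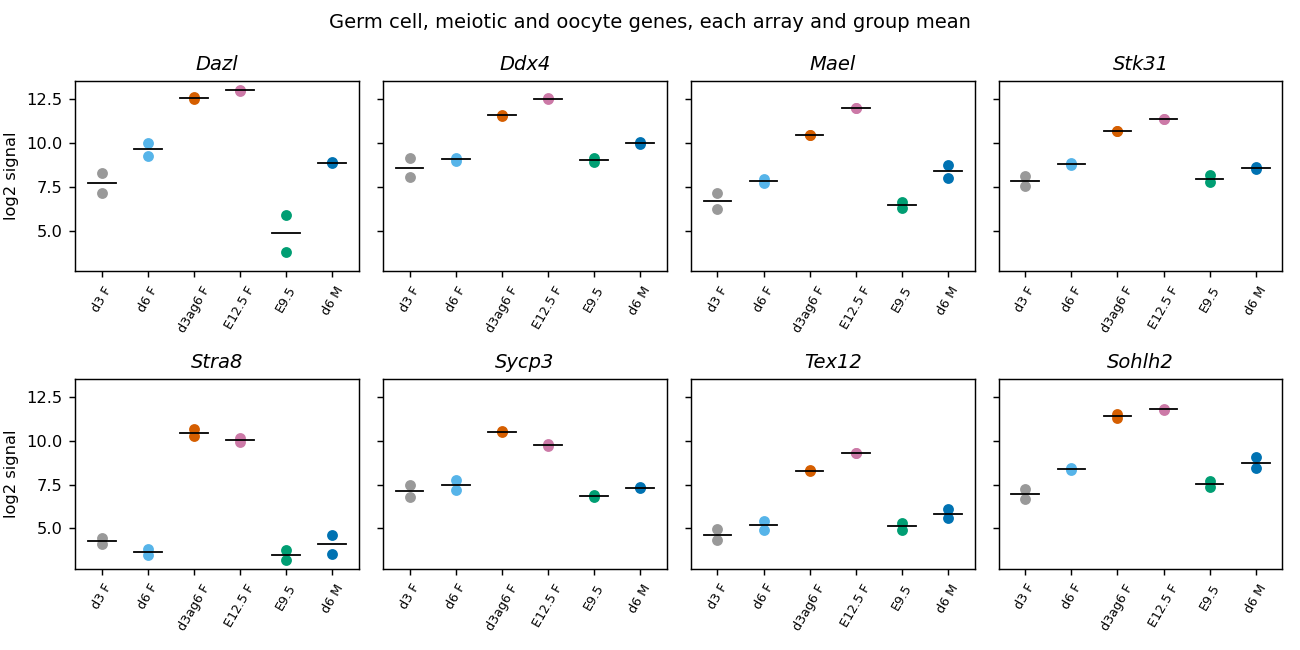
Log2 signal (y axis) of 8 germ cell genes in each of the 12 arrays, by group (x axis); points are arrays and bars mark the group mean of 2 arrays. Stra8 averages 10.45 in d3ag6 PGCLCs and 10.04 in E12.5 PGCs, against 3.65 in d6 female PGCLCs and 3.47 in E9.5 PGCs.

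Some markers of other cells were higher in d3ag6 cells in the same comparison. Genes with a high change were Ctss, cathepsin S of antigen-presenting cells (8.85 ± 0.40 against 1.27 ± 0.56; 7.58, SE 1.37, adjusted p = 0.0159), and Lyz1, a lysozyme (9.41 ± 0.22 against 2.46 ± 0.21; 6.95, SE 0.96, adjusted p = 0.00519). Their d6 female means lie below 4.81, and with values below that level set to it the changes were 4.03 and 4.60. Ctss lost its call without any 1 of the 4 arrays compared (adjusted p = 0.0603 to 0.116). Of 12 blood and macrophage markers, 2 rose, Lyz2 (4.04, SE 0.32, adjusted p = 0.000599) and the myeloid signalling adaptor Tyrobp (1.86, SE 0.23, adjusted p = 0.00309). The other 10 did not pass, with 4 higher adjusted over the list alone (median 0.164, adjusted p = 0.105). The list of gonadal somatic cell markers was higher, with 3 of 14 genes up, 11 not called and 4 up adjusted over the list alone (median 0.697, adjusted p = 0.00238; adjusted p = 0.241 with an estimated correlation). Amhr2, the anti-Mullerian hormone receptor, rose by 3.12 (SE 0.31). Of 17 mesenchyme markers, 2 rose, 1 fell and 14 did not pass, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.521).

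**Figure D3:**
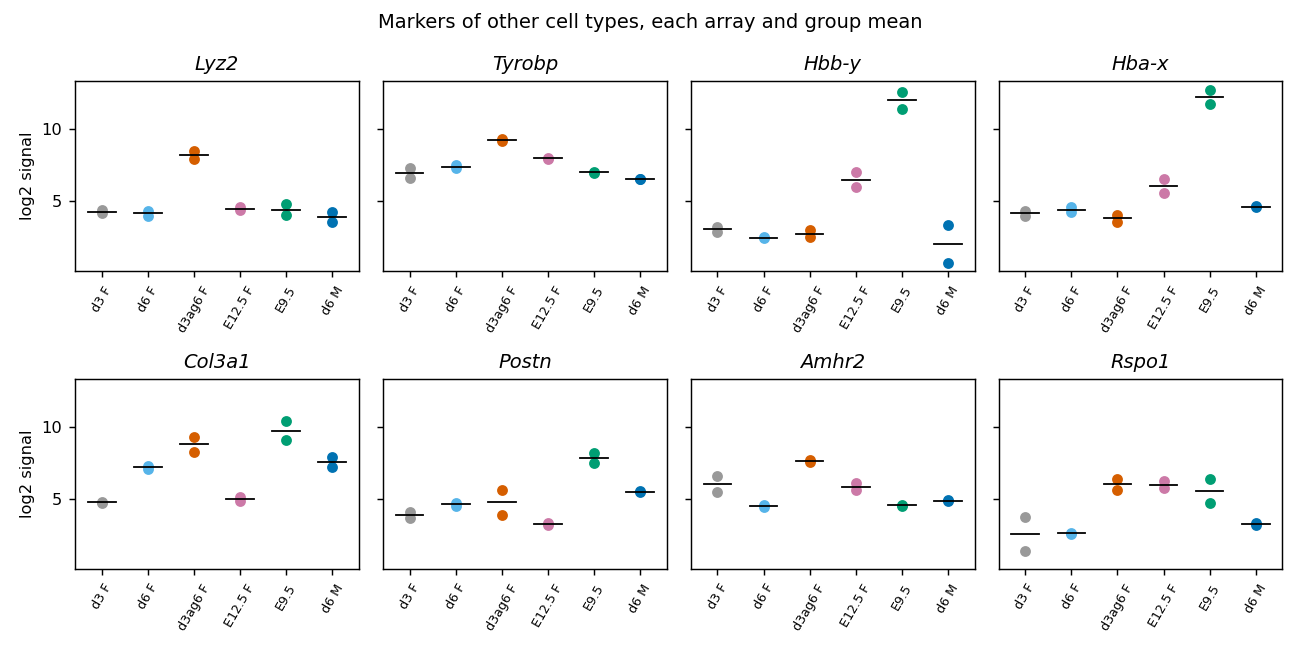
Log2 signal (y axis) of 8 genes known from macrophages, blood, mesenchyme and gonadal somatic cells in each of the 12 arrays, by group (x axis); points are arrays and bars mark the group mean of 2 arrays. Lyz2 and Tyrobp are higher in d3ag6 than in d6 female PGCLCs (changes of 4.04 and 1.86), and Hbb-y averages 11.98 in E9.5 PGCs.

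Other genes with large changes in d3ag6 cells were Akr1cl, of the aldo-keto reductase family (5.60, SE 0.34), Sod3, the extracellular superoxide dismutase (5.36, SE 0.60), Gad1, which makes GABA from glutamate (5.00, SE 0.59), and Zfp503 (4.93, SE 0.65). Naprt, of nicotinate salvage, changed by -4.01 (SE 0.17, adjusted p = 2.38e-05), Bcl3, of the I-kappa-B family, by -4.35 (SE 0.33), and Socs3, an inhibitor of cytokine signalling, by -3.46 (SE 0.46). The somatic mesoderm list was lower, with 5 of 30 genes down and 25 not called, and 6 lower and 1 higher adjusted over the list alone (median -0.409, adjusted p = 0.00331; adjusted p = 0.12 with an estimated correlation). The pluripotency list was lower, with 2 of 26 genes down, Nanog (-1.99) and Tfcp2l1 (-0.86), 24 not called and 3 lower adjusted over the list alone (median -0.286, adjusted p = 0.00624; adjusted p = 0.127 with an estimated correlation). Neither member was called without any 1 of the 4 arrays compared (adjusted p = 0.0583 to 0.259 for Nanog and 0.0603 to 0.171 for Tfcp2l1).

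The list calls of endothelial markers (median -0.577, adjusted p = 0.0101; adjusted p = 0.457 with an estimated correlation), hypoxia and glycolysis (median 0.285, adjusted p = 0.0285; adjusted p = 0.574 with an estimated correlation) and PGC specification (median -0.281, adjusted p = 0.0344; adjusted p = 0.355 with an estimated correlation) rested on few members. In limma, 0 of 13 endothelial genes were called, over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05. Of 28 hypoxia genes 1 was called higher and 1 lower, neither without any 1 of the 4 arrays compared (adjusted p = 0.0763 to 0.164 for P4ha2 and 0.0933 to 0.153 for Hk1), and 26 did not pass, with the same numbers adjusted over the list alone. The only PGC specification gene called of 19, the integrin subunit Itgb3, rose (0.79, SE 0.17), against the direction of its list, and it was the 1 gene called adjusted over the list alone, a call over all genes that was lost without any 1 of the 4 arrays compared (adjusted p = 0.124 to 0.144). The endothelial call was lost without d6 female replicate 1 (adjusted p = 0.137) or d3ag6 replicate 1 (adjusted p = 0.106), and its mean went from -0.618 to -0.965 without d6 female replicate 2. The hypoxia call was lost without d6 female replicate 1 (adjusted p = 0.332) or d3ag6 replicate 2 (adjusted p = 0.0896), and the PGC specification call was lost without d6 female replicate 1 (adjusted p = 0.0656) or d3ag6 replicate 2 (adjusted p = 0.174). The endothelial and hypoxia calls were also lost with the stricter filter (adjusted p = 0.0655 for each), and the hypoxia call with the values as deposited (adjusted p = 0.0864). With only the 8 arrays coded EA1013, a setting chosen after the data were seen, the PGC specification call was lost (adjusted p = 0.0508).

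In all, 859 genes were called between d3ag6 and d6 female PGCLCs, 542 higher and 317 lower in d3ag6, and 582 changed at least 2-fold. With the values as deposited the split was 659 higher and 236 lower. Without d6 female replicate 1, d6 female replicate 2, d3ag6 replicate 1 or d3ag6 replicate 2 the count was 193, 356, 283 or 196.

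Set against the d3 cells from which they were made, d3ag6 PGCLCs had higher Lyz1 (9.41 ± 0.22 against 1.96 ± 0.55; 7.45, SE 0.96, adjusted p = 0.00187) and Tex13b (6.52, SE 0.74), and lower Psmb8 (-5.35, SE 0.39), Gbp3, an interferon-induced GTPase (-4.77, SE 0.38), and Wnt5a (-4.76, SE 0.56). Stra8 rose by 6.17 (SE 0.36, adjusted p = 6.31e-05), Dazl by 4.86 (SE 0.61), Sycp3 by 3.37 (SE 0.25) and Ddx4 by 2.97 (SE 0.29). Dppa3 rose by 0.55 (SE 0.14, adjusted p = 0.036), a call lost without any 1 of the 4 arrays compared. Prdm1 (0.13, adjusted p = 0.835) and Xist (-0.50, adjusted p = 0.326) did not pass. The gonadal germ cell list had 17 of 28 genes up, 11 not called and 21 up adjusted over the list alone (median 2.043, camera adjusted p = 1.08e-18; adjusted p = 0.0817 with an estimated correlation). The meiosis list had 17 of 30 up, 13 not called and 21 up adjusted over the list alone (median 1.425, adjusted p = 2.64e-13; adjusted p = 0.12 with an estimated correlation). Mov10l1, a helicase of the piRNA pathway, rose by 3.28 (SE 0.27).

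Somatic mesoderm genes were lower in d3ag6 than in d3 cells, with 12 of 30 down, 1 up, 17 not called, and 12 down and 1 up adjusted over the list alone (median -1.052, adjusted p = 2.25e-10). This was the only list call of the 8 comparisons that held with an estimated correlation (adjusted p = 0.045 with an estimated correlation). Evx1 changed by -4.52 (SE 0.26) and the caudal homeobox gene Cdx2 by -2.94 (SE 0.31). Hypoxia and glycolysis genes were higher, with 8 of 28 up, 20 not called and 12 up adjusted over the list alone (median 0.465, adjusted p = 8.56e-05; adjusted p = 0.384 with an estimated correlation). The primed epiblast list was lower, with 3 of 13 genes down, 10 not called and 4 down adjusted over the list alone (median -0.341, adjusted p = 0.0124; adjusted p = 0.329 with an estimated correlation). Blood and macrophage markers were higher, with 3 of 12 up, 9 not called and 3 up adjusted over the list alone (median 0.289, adjusted p = 0.0344; adjusted p = 0.506 with an estimated correlation). Without d3 replicate 1 (adjusted p = 0.0911) or d3ag6 replicate 2 (adjusted p = 0.0854) the call was lost. It was also lost with only the arrays of the groups compared (adjusted p = 0.0776) and with only the 8 arrays coded EA1013 (adjusted p = 0.0576), a setting chosen after the data were seen. Lyz2 (3.93, SE 0.32) and Tyrobp (2.30, SE 0.23) rose, and so did the mesenchymal collagen Col3a1 (4.02, SE 0.46).

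The d3ag6 and d3 cells differed in 1430 genes, 780 higher and 650 lower in d3ag6. The count fell without any 1 of the 4 arrays compared, and the balance turned without d3ag6 replicate 2. The pluripotency list was lower (4 of 26 down, 1 up, 21 not called, and 6 down and 2 up adjusted over the list alone; median -0.263, adjusted p = 0.0415; adjusted p = 0.239 with an estimated correlation). Without d3 replicate 2 (adjusted p = 0.0756) or d3ag6 replicate 2 (adjusted p = 0.0629) the call was lost. It was also lost with the stricter filter (adjusted p = 0.195), the mean of all probe sets (adjusted p = 0.112) or only the arrays of the groups compared (adjusted p = 0.0607).

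How near aggregated PGCLCs came to PGCs of the embryo was read from d3ag6 against E12.5 PGCs. Dazl (-0.43, adjusted p = 0.746), Ddx4 (-0.96, adjusted p = 0.0758), Sycp3 (0.74, adjusted p = 0.11) and Stra8 (0.41, adjusted p = 0.58) did not pass, and neither did Prdm1 (0.56, adjusted p = 0.262), Dppa3 (0.06, adjusted p = 0.851) or Xist (-0.25, adjusted p = 0.679). Genes higher in d3ag6 cells were the neuropeptide gene Nts (7.65, SE 0.79), at 0 in 1 of the E12.5 arrays, Lyz1 (7.29, SE 0.96), Nupr1, a stress-induced nuclear protein (6.07, SE 0.73), also at 0 in 1 E12.5 array, Gad1 (5.43, SE 0.59) and the Nodal antagonist Lefty2 (10.12 ± 0.08 against 5.18 ± 0.32; 4.94, SE 0.29, adjusted p = 9.54e-05). Lower in d3ag6 cells were Id1, a target of BMP signalling (7.02 ± 0.58 against 11.54 ± 0.18; -4.52, SE 0.29, adjusted p = 9.54e-05), the receptor tyrosine kinase Met (-4.29, SE 0.33), Dync1i1, of the dynein motor (-3.92, SE 0.25), Gbx2 (-3.69, SE 0.24) and the ETS factor Etv4 (-3.35, SE 0.18).

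Hypoxia and glycolysis genes were higher in d3ag6 than in E12.5 cells, with 14 of 28 up, 14 not called and 19 up adjusted over the list alone (median 1.167, camera adjusted p = 6.09e-13; adjusted p = 0.151 with an estimated correlation). The glucose transporters Slc2a1 (2.46, SE 0.22) and Slc2a3 (1.40, SE 0.16), triosephosphate isomerase Tpi1 (2.27, SE 0.21) and the angiogenic factor Vegfa (2.57, SE 0.30) rose. BMP, WNT and retinoic acid response genes were lower, with 8 of 21 down, 13 not called and 9 down adjusted over the list alone (median -0.73, adjusted p = 3.64e-06; adjusted p = 0.0817 with an estimated correlation). Id4 changed by -2.80 (SE 0.27). The gonadal germ cell list was lower, with 5 of 28 down, 23 not called and 8 down adjusted over the list alone (median -0.477, adjusted p = 0.00085; adjusted p = 0.329 with an estimated correlation). The meiosis list was lower as well, with 4 of 30 down, 1 up, 25 not called, and 8 down and 2 up adjusted over the list alone (median -0.396, adjusted p = 0.00229; adjusted p = 0.386 with an estimated correlation). Tex15 changed by -1.64 (SE 0.17), whereas Meiob, which acts in meiotic recombination, rose by 2.94 (SE 0.41). Of the 30 somatic mesoderm genes, 9 fell and 21 did not pass, and 9 fell adjusted over the list alone (median -0.164, adjusted p = 0.00118; adjusted p = 0.0962 with an estimated correlation), among them Id1, Id3 and Msx1, which the BMP list also holds.

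Endothelial markers were higher in d3ag6 cells, with 3 of 13 up, 10 not called and 5 up adjusted over the list alone (median 0.961, adjusted p = 0.00429; adjusted p = 0.386 with an estimated correlation). Mesenchyme markers were higher, with 3 of 17 up, 14 not called and 5 up adjusted over the list alone (median 0.599, adjusted p = 0.0184; adjusted p = 0.561 with an estimated correlation). Without d3ag6 replicate 2 (adjusted p = 0.176) the call was lost, as it was with the stricter filter (adjusted p = 0.403), which left 6 of the 17 genes. Col3a1 rose by 3.80 (SE 0.46). Of 12 blood and macrophage markers, 3 rose, 2 fell and 7 did not pass, with 5 up and 2 down adjusted over the list alone (median 0.333, adjusted p = 0.319). Lyz2 (3.72, SE 0.32) and Cd68, of macrophage lysosomes (2.34, SE 0.32), were higher. Immediate early and stress genes were higher, with 4 of 22 up, 1 down, 17 not called, and 5 up and 1 down adjusted over the list alone (median 0.32, adjusted p = 0.0309; adjusted p = 0.386 with an estimated correlation). Without d3ag6 replicate 1 (adjusted p = 0.108) the call was lost. The pluripotency list was higher with 5 of 26 up, 1 down, 20 not called, and 8 up and 2 down adjusted over the list alone (median 0.253, adjusted p = 0.0499; adjusted p = 0.241 with an estimated correlation). Without d3ag6 replicate 1 (adjusted p = 0.0772), d3ag6 replicate 2 (adjusted p = 0.0555) or E12.5 replicate 2 (adjusted p = 0.0881) the call was lost. It was also lost with the stricter filter (adjusted p = 0.145), the values as deposited (adjusted p = 0.0837) or the mean of all probe sets (adjusted p = 0.31).

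Between d3ag6 PGCLCs and E12.5 PGCs 1213 genes were called, 800 higher and 413 lower in d3ag6. Without d3ag6 replicate 1, d3ag6 replicate 2, E12.5 replicate 1 or E12.5 replicate 2 the count was 573, 417, 363 or 388. Strain also differed, with PGCLCs of C57BL/6 and PGCs of mixed C57BL/6 and BDF1 background.

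In the embryo, the step from E9.5 to E12.5 raised the same meiotic gene: Stra8 rose from 3.47 ± 0.42 to 10.04 ± 0.17 (6.57, SE 0.36, adjusted p = 3.64e-05). Dazl, at 4.86 ± 1.49 at E9.5, rose by 8.14 (SE 0.61, adjusted p = 8.1e-05), Ddx4 by 3.51 (SE 0.29), Sycp3 by 2.94 (SE 0.25) and Ccdc172, at 0 in 1 of the E9.5 arrays, by 6.08 (SE 0.83). Prdm1 (-0.77, adjusted p = 0.068), Dppa3 (-0.01, adjusted p = 0.974) and Xist (-0.02, adjusted p = 0.965) did not pass. The Y-linked genes Kdm5d, a histone demethylase (-6.20, SE 0.64), and Eif2s3y, a translation factor subunit (-5.81, SE 0.52), were lower in the female E12.5 cells than in E9.5 cells, as was the embryonic globin Hba-x (-6.18, SE 0.39). Gonadal germ cell genes were higher, with 22 of 28 up, 6 not called and 24 up adjusted over the list alone (median 2.776, camera adjusted p = 2.33e-14; adjusted p = 0.0962 with an estimated correlation). Meiosis genes were higher as well, with 22 of 30 up, 8 not called and 24 up adjusted over the list alone (median 2.332, adjusted p = 1.73e-12; adjusted p = 0.123 with an estimated correlation). Mael, of the piRNA pathway (5.50, SE 0.33), Stk31 (3.39, SE 0.20), Tex12 (4.16, SE 0.27) and Zglp1 (4.38, SE 0.29) rose. Oocyte genes were higher, with 6 of 12 up, 6 not called and 8 up adjusted over the list alone (median 0.874, adjusted p = 0.0061; adjusted p = 0.134 with an estimated correlation). They included Sohlh2 (4.27, SE 0.26). This call was lost without the filter on dim genes (adjusted p = 0.158).

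Mesenchyme and blood markers were lower at E12.5 than at E9.5, while endothelial (adjusted p = 0.0503), neural (adjusted p = 0.264), gonadal somatic (adjusted p = 0.437) and gut and visceral endoderm markers (adjusted p = 0.503) were not called. Of 17 mesenchyme markers 10 fell and 7 did not pass, and 10 fell adjusted over the list alone (median -1.597, adjusted p = 3.64e-06; adjusted p = 0.329 with an estimated correlation). The collagen Col3a1 changed by -4.74 (SE 0.46) and the matrix protein Postn by -4.63 (SE 0.48). Of 12 blood and macrophage markers 4 fell, 1 rose and 7 did not pass, with 4 down and 1 up adjusted over the list alone (median -0.574, adjusted p = 0.0152; adjusted p = 0.406 with an estimated correlation). Without E9.5 replicate 1 (adjusted p = 0.0513) the call was lost, and with the stricter filter as well (adjusted p = 0.155). Those that fell were of the red cell lineage, Hba-x, Hbb-y (-5.50, SE 0.74), Hbb-bh1 (-4.20, SE 0.51) and the haem synthesis enzyme Alas2 (-4.62, SE 0.49). Somatic mesoderm genes were lower, with 9 of 30 down, 3 up, 18 not called, and 11 down and 3 up adjusted over the list alone (median -0.433, adjusted p = 0.0284; adjusted p = 0.204 with an estimated correlation). This call was lost with the values as deposited (adjusted p = 0.0519). With the stricter filter, which left 11 of the 30 genes, it was lost with a list mean of -0.179 (adjusted p = 0.941) in place of -0.934. Hypoxia and glycolysis genes were lower, with 10 of 28 down, 1 up, 17 not called, and 11 down and 3 up adjusted over the list alone (median -0.198, adjusted p = 0.024; adjusted p = 0.574 with an estimated correlation). This call was lost without E9.5 replicate 1 (adjusted p = 0.0883), and with the values as deposited as well (adjusted p = 0.0575).

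PGC specification genes were lower at E12.5, with 5 of 19 down, 2 up, 12 not called, and 9 down and 2 up adjusted over the list alone (median -0.31, adjusted p = 0.0317; adjusted p = 0.355 with an estimated correlation). Without E9.5 replicate 2 (adjusted p = 0.128) the call was lost, as it was with the values as deposited (adjusted p = 0.0915) or only the arrays compared (adjusted p = 0.0566). Alpl, the alkaline phosphatase long used to stain PGCs, changed by -1.85 (SE 0.34), and Ifitm3 by -1.25 (SE 0.15). Primed epiblast genes were lower, with 4 of 13 down, 9 not called, and 4 down and 1 up adjusted over the list alone (median -0.215, adjusted p = 0.0466; adjusted p = 0.386 with an estimated correlation). Its call was lost without E12.5 replicate 2 (adjusted p = 0.0601) or E9.5 replicate 1 (adjusted p = 0.25), and its mean went from -0.442 to -0.772 without E9.5 replicate 2. The values as deposited (adjusted p = 0.0631), the mean of all probe sets (adjusted p = 0.159) or only the arrays compared (adjusted p = 0.0558) also ended it. Of 5 Y-linked genes 3 fell, 1 was higher and 1 did not pass, with 4 down and 1 up adjusted over the list alone (median -1.268, adjusted p = 0.0499; adjusted p = 0.316 with an estimated correlation). Leaving out E9.5 replicate 1 (adjusted p = 0.0706) or E9.5 replicate 2 (adjusted p = 0.083) ended the call. The values as deposited (adjusted p = 0.0915), no filter (adjusted p = 0.0506) or only the arrays compared (adjusted p = 0.0638) also ended it. The higher value was that of the probe set named Zfy2 (3.20, SE 0.24), which stood at 7.32 to 8.13 in all 8 arrays coded EA1013, all of female cells, and at 4.42 to 5.06 in the other 4. It is not read as Y-linked expression. In all, 3170 genes were called, 1727 higher and 1443 lower at E12.5. The values as deposited gave 1350 higher and 1689 lower, where the median change of all genes was 0 in place of 0.08. The count fell without any 1 of the 4 arrays compared.

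The culture step (d3ag6 minus d6 female, which differ by aggregation and by 3 days) and the embryonic step (E12.5 minus E9.5) share no array, so their changes could be set against each other. Across 13436 genes, which are not independent replicates, they correlated with r = 0.38 (jackknife SE 0.064 over arrays; Spearman's rho 0.374). Of the 520 genes called in both, 470 (90.4%) changed the same way, 311 higher and 159 lower, where independent lists would share 69.7 and 34. Stra8, Sycp3, Ddx4, Tex12, Stk31 and Sohlh2 were among the genes that rose in both steps. The array code differed between the groups of the embryonic step and not between those of the culture step.

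Female d6 PGCLCs were then set against E9.5 PGCs. Large differences were in embryonic globins of red cells, whose PGCLC means lie below 4.81: Hbb-y was 2.44 ± 0.06 in PGCLCs and 11.98 ± 0.79 in E9.5 cells (-9.54, SE 0.74, adjusted p = 0.000197), and Hba-x 4.39 ± 0.24 and 12.23 ± 0.71 (-7.84, SE 0.39, adjusted p = 4.08e-05). Zfp503 (-6.91, SE 0.65), the nuclear receptor Nr2f1 (-5.82, SE 0.54), and the Y-linked Kdm5d (-5.54, SE 0.64) and Eif2s3y (-5.13, SE 0.52) were also lower in the female PGCLCs. Higher in them were Fabp3, a fatty acid-binding protein (11.30 ± 0.15 against 5.00 ± 0.65; 6.30, SE 0.34, adjusted p = 4.47e-05), Nupr1 (6.56, SE 0.73), cytidine deaminase Cda (5.76, SE 0.38), Bcl3 (5.52, SE 0.33) and Dazl (9.63 ± 0.52 against 4.86 ± 1.49; 4.77, SE 0.61, adjusted p = 0.00161). Ddx4 (0.04, adjusted p = 0.942), Sycp3 (0.62, adjusted p = 0.141), Stra8 (0.18), Prdm1 (0.08), Dppa3 (-0.07) and Xist (-0.24) did not pass.

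Mesenchyme, mesoderm, red cell, neural and gonadal somatic markers were lower in the PGCLCs than in E9.5 cells. Whether other cells were sorted with the E9.5 PGCs was not tested, and they would enter each comparison with E9.5. Mesenchyme markers had 7 of 17 genes down, 10 not called and 7 down adjusted over the list alone (median -1.004, camera adjusted p = 8.56e-05; adjusted p = 0.355 with an estimated correlation). With the stricter filter, which left 6 of them, the call was lost (list mean -0.677, adjusted p = 0.202, in place of -1.382). Postn changed by -3.24 (SE 0.48) and the transcription factor Twist1 by -4.33 (SE 0.73). Somatic mesoderm genes had 10 of 30 down, 1 up, 19 not called, and 12 down and 1 up adjusted over the list alone (median -0.462, adjusted p = 0.000197; adjusted p = 0.0899 with an estimated correlation). Blood and macrophage markers had 4 of 12 down, all of the red cell lineage, 1 up, 7 not called, and 5 down and 1 up adjusted over the list alone (median -0.313, adjusted p = 0.00624; adjusted p = 0.385 with an estimated correlation). Neural markers had 3 of 11 down, 8 not called and 6 down adjusted over the list alone (median -0.774, adjusted p = 0.00721; adjusted p = 0.386 with an estimated correlation). The call was lost without E9.5 replicate 1 (adjusted p = 0.144). Gonadal somatic cell markers had 4 of 14 down, 10 not called and 6 down adjusted over the list alone (median -0.633, adjusted p = 0.00904; adjusted p = 0.329 with an estimated correlation). Endothelial markers were higher, with 4 of 13 up, 9 not called and 5 up adjusted over the list alone (median 0.893, adjusted p = 0.0101; adjusted p = 0.457 with an estimated correlation). Without d6 female replicate 1 (adjusted p = 0.114) or E9.5 replicate 2 (adjusted p = 0.0873) the call was lost, as it was with the stricter filter (adjusted p = 0.14).

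Gonadal germ cell genes were higher in d6 female PGCLCs than in E9.5 PGCs, with 10 of 28 up, 18 not called and 12 up adjusted over the list alone (median 0.85, adjusted p = 0.000364; adjusted p = 0.329 with an estimated correlation). Pluripotency genes were higher, with 8 of 26 up, 2 down, 16 not called, and 11 up and 2 down adjusted over the list alone (median 0.511, adjusted p = 0.0089; adjusted p = 0.134 with an estimated correlation). BMP, WNT and retinoic acid response genes were lower, with 9 of 21 down, 2 up, 10 not called, and 9 down and 4 up adjusted over the list alone (median -0.356, adjusted p = 0.0137; adjusted p = 0.213 with an estimated correlation). With the stricter filter the call was lost (list mean -0.541, adjusted p = 0.172, in place of -0.767). Cell cycle genes were lower, with 3 of 35 down, 32 not called and 3 down adjusted over the list alone (median -0.151, adjusted p = 0.0223; adjusted p = 0.552 with an estimated correlation). Without d6 female replicate 1 (adjusted p = 0.0895) or E9.5 replicate 2 (adjusted p = 0.268) the call was lost, and also with the values as deposited (adjusted p = 0.135) or the stricter filter (adjusted p = 0.104). Over all genes 1872 were called, 1119 higher and 753 lower in the PGCLCs. With the values as deposited there were 763 higher and 950 lower, where the median change of all genes was -0.035 in place of 0.065. The count fell without either d6 female array. There were 862 higher and 426 lower without E9.5 replicate 1, and 742 higher and 611 lower without E9.5 replicate 2.

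Sex was the difference by label between d6 female and d6 male PGCLCs. The Y-linked Eif2s3y was 3.24 ± 0.02 in female and 8.69 ± 0.41 in male cells (-5.45, SE 0.52, adjusted p = 0.0056). With all its probe sets averaged it was not called (-1.97, adjusted p = 0.0747). Kdm5d was -4.13 (SE 0.64, adjusted p = 0.0235), a call lost without any 1 of the 4 arrays compared (adjusted p = 0.0535 to 0.128). Cap1, an actin-binding protein, was higher in female cells (9.68 ± 0.31 against 4.07 ± 0.31; 5.61, SE 0.42, adjusted p = 0.00329), and Myh6, a cardiac myosin heavy chain, lower (-3.63, SE 0.32, adjusted p = 0.00373). Xist, the RNA that coats the inactive X chromosome, did not pass (0.51, adjusted p = 0.373), nor did Ddx4 (-0.92, adjusted p = 0.157), Dazl (0.75, adjusted p = 0.542), Sycp3 (0.14), Stra8 (-0.44), Prdm1 (0.07) or Dppa3 (0.03). Of 5 Y-linked genes 3 were lower in female cells, 1 was higher and 1 did not pass, with the same numbers adjusted over the list alone (median -2.297, camera adjusted p = 0.00624; adjusted p = 0.151 with an estimated correlation). The higher one was the probe set named Zfy2 (2.85, SE 0.24, adjusted p = 0.00329), whose signal in female cells is not read as Y-linked expression.

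Hypoxia and glycolysis genes were higher in d6 female than in d6 male cells, with 5 of 28 up, 23 not called and 14 up adjusted over the list alone (median 0.83, adjusted p = 1.07e-08; adjusted p = 0.241 with an estimated correlation). Lactate dehydrogenase Ldha was higher by 2.38 (SE 0.29, adjusted p = 0.0121). It lost its call without d6 female replicate 2 (adjusted p = 0.077) or d6 male replicate 2 (adjusted p = 0.0645). Endothelial markers were lower (median -0.85, adjusted p = 0.000943; adjusted p = 0.378 with an estimated correlation), with 4 of 13 lower adjusted over the list alone. In limma 0 were called over all genes tested, with 5 at an unadjusted p under 0.05. This list call was lost without d6 female replicate 2 (adjusted p = 0.052). Mesenchyme markers were lower (median -0.503, adjusted p = 0.0288; adjusted p = 0.574 with an estimated correlation). Among them limma called 0 of 17, over all genes tested or adjusted over the list alone, with 1 at an unadjusted p under 0.05. Their list call was lost without d6 female replicate 2 (adjusted p = 0.0682) or d6 male replicate 2 (adjusted p = 0.0914), without the filter (adjusted p = 0.209) or with the values as deposited (adjusted p = 0.0857). The 436 genes of chromosome 16, singled out after the values were seen, were lower in female cells than other autosomal genes by a median of -0.274 (camera adjusted p = 2.71e-07 over 152 tests of autosomes in comparisons; adjusted p = 0.0658 with an estimated correlation). Relative to the mean of each gene, they exceeded other autosomal genes by 0.259 and 0.219 in the d6 male arrays, against -0.079 to -0.013 in the other 10. Over all genes 197 were called, 130 higher and 67 lower in female cells. With the deposited values there were 82 higher and 115 lower, where the median change of all genes was -0.055 in place of 0.045. The count was 12 without d6 female replicate 1, 12 without d6 female replicate 2 and 29 without d6 male replicate 2, while without d6 male replicate 1 there were 195 higher and 44 lower. Without the filter on dim genes it was 38, and with only the arrays of the groups compared it was 2. Of the 16 genes with the largest changes 3, Cap1, Eif2s3y and Myh6, kept their call with each array left out.

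Male d6 PGCLCs and E9.5 PGCs each had 1 array under EA0831 and 1 under EA0842, so that their codes were balanced. Hbb-y (-9.98, SE 0.74), Hba-x (-7.64, SE 0.39) and Foxc2 (-5.57, SE 0.75) were lower in the PGCLCs, and Nupr1 (6.32, SE 0.73), Fabp3 (5.64, SE 0.34) and Mymx, a muscle fusion factor (5.55, SE 0.74), higher. Dazl rose by 4.02 (SE 0.61, adjusted p = 0.0038), while Ddx4 (0.96, adjusted p = 0.071) and Xist (-0.74, adjusted p = 0.149) did not pass. Endothelial markers were higher, with 6 of 13 up, 7 not called and 9 up adjusted over the list alone (median 1.5, camera adjusted p = 4.16e-07; adjusted p = 0.228 with an estimated correlation). They included Tek (2.39, SE 0.34). Somatic mesoderm genes were lower, with 9 of 30 down, 2 up, 19 not called, and 11 down and 2 up adjusted over the list alone (median -0.659, adjusted p = 3.17e-05; adjusted p = 0.0817 with an estimated correlation). BMP, WNT and retinoic acid response genes were lower too, with 7 of 21 down, 2 up, 12 not called, and 8 down and 2 up adjusted over the list alone (median -0.739, adjusted p = 0.000193; adjusted p = 0.0962 with an estimated correlation).

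Germ cell and pluripotency genes were higher in d6 male PGCLCs than in E9.5 PGCs. The gonadal germ cell list had 8 of 28 up, 20 not called and 12 up adjusted over the list alone (median 0.601, adjusted p = 0.000822; adjusted p = 0.329 with an estimated correlation). The pluripotency list had 6 of 26 up, 2 down, 18 not called, and 10 up and 2 down adjusted over the list alone (median 0.481, adjusted p = 0.00085; adjusted p = 0.0962 with an estimated correlation). Blood and macrophage markers had 4 of 12 down, 8 not called, and 4 down and 1 up adjusted over the list alone (median -0.506, adjusted p = 0.00112; adjusted p = 0.329 with an estimated correlation). Mesenchyme markers had 7 of 17 down, 1 up, 9 not called, and 8 down and 2 up adjusted over the list alone (median -0.859, adjusted p = 0.00875; adjusted p = 0.519 with an estimated correlation). With the stricter filter, which left 6 of them, the call was lost (list mean -0.153, adjusted p = 0.976, in place of -1.062). Without E9.5 replicate 1 (adjusted p = 0.061) or d6 male replicate 1 (adjusted p = 0.0592) the call was lost. Gonadal somatic cell markers had 5 of 14 down, 9 not called and 7 down adjusted over the list alone (median -0.853, adjusted p = 0.0188; adjusted p = 0.352 with an estimated correlation). Without d6 male replicate 1 (adjusted p = 0.072) the call was lost. Gut and visceral endoderm markers had 1 of 18 down, the forkhead gene Foxa1 (-2.74, SE 0.43; -0.61 with values below 4.81 set to it), 17 not called and 1 down adjusted over the list alone (median -0.479, adjusted p = 0.00597; adjusted p = 0.386 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.155). Genes of hypoxia and glycolysis were lower, with 7 of 28 down, 3 up, 18 not called, and 9 down and 4 up adjusted over the list alone (median -0.284, adjusted p = 0.0171; adjusted p = 0.571 with an estimated correlation). Leaving out E9.5 replicate 1 (adjusted p = 0.106) or d6 male replicate 2 (adjusted p = 0.0698) ended the call. Immediate early and stress genes were higher, with 6 of 22 up, 1 down, 15 not called, and 6 up and 2 down adjusted over the list alone (median 0.297, adjusted p = 0.0263; adjusted p = 0.385 with an estimated correlation). Without E9.5 replicate 2 (adjusted p = 0.137) or d6 male replicate 1 (adjusted p = 0.156) the call was lost.

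The comparison of d6 male PGCLCs with E9.5 PGCs called 1424 genes, 812 higher and 612 lower in the PGCLCs. Without E9.5 replicate 2 the balance turned, with 514 higher and 591 lower, as it did without d6 male replicate 1, with 487 and 491. There were 627 higher and 342 lower without E9.5 replicate 1. Chromosome 16 genes exceeded other autosomal genes by a median of 0.278 (adjusted p = 1.84e-05; adjusted p = 0.0745 with an estimated correlation), with 54 higher, 6 lower and 73.2% above 0, against 48.8% of other autosomal genes. The count was 849 without d6 male replicate 2, and 2004 with the array code as a block, a fit chosen after the data were seen in which all 12 list calls held.

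Genes of the X chromosome were followed as a group, since the dosage of X-linked genes can differ between the sexes and between stages of female germ cells. The median change of 444 X-linked genes differed from that of autosomal genes by -0.202 log2 units between d3 and d6 female cells (camera adjusted p = 3.19e-06; adjusted p = 0.179 with an estimated correlation). Of the X-linked genes 36 were lower and 7 higher, and 30% of X-linked genes but 49.2% of autosomal genes above 0. The same difference was -0.117 between d3 and d3ag6 (adjusted p = 0.011; adjusted p = 0.486 with an estimated correlation), with 52 lower and 21 higher. That call was lost without d3 replicate 1 (-0.117, adjusted p = 0.236) or d3ag6 replicate 2 (-0.082, adjusted p = 0.0533), and it was -0.188 without d3ag6 replicate 1. Between d6 female and d6 male cells it was 0.063 (adjusted p = 0.648; -0.021 without d6 male replicate 1), with 4 X-linked genes higher and 4 lower. A fixed list of 56 widely expressed X-linked genes was lower at d6 than at d3, with 4 down, 52 not called and 9 down adjusted over the list alone (median -0.215, adjusted p = 0.000197; adjusted p = 0.329 with an estimated correlation).

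**Figure D4:**
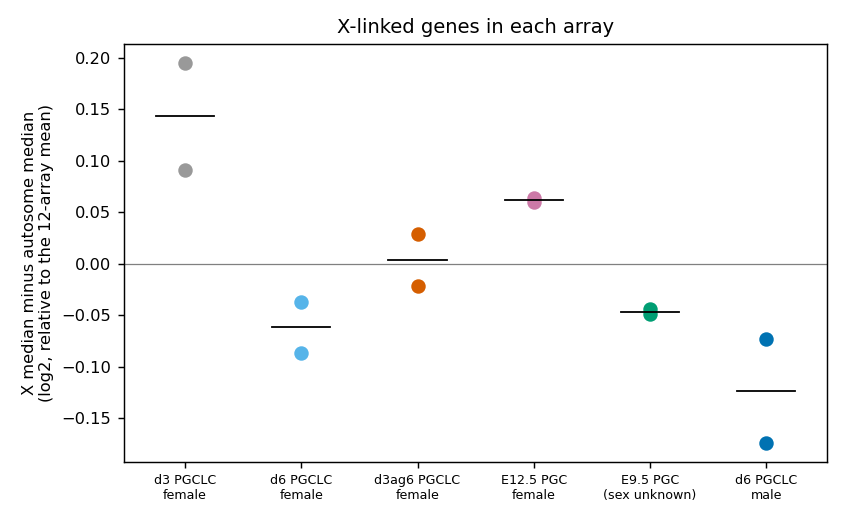
Median of X-linked genes minus median of autosomal genes (y axis, log2, each gene relative to its mean over the 12 arrays) for each array, by group (x axis); points are arrays and bars mark the group mean of 2 arrays. The d3 arrays are at 0.195 and 0.091, the d6 female arrays at -0.037 and -0.087, and the d6 male arrays at -0.174 and -0.073.

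Across the 23 lists and 8 comparisons, 73 of 184 list tests were called by camera with its preset correlation, and 1 with an estimated correlation. Cell cycle inhibitors and the DNA methylation machinery were not called in any comparison, with lowest adjusted p of 0.0601 and 0.0789. Of 15 cell cycle inhibitors, 3 rose, 1 fell and 11 did not pass in d6 male PGCLCs against E9.5 PGCs, with 4 up and 1 down adjusted over the list alone, and Ccng1, a p53 target, rose by 2.24 (SE 0.16). Of 21 DNA methylation genes 1 fell and 20 did not pass between d6 female and d3ag6 cells, with 1 down adjusted over the list alone, and that gene, Gadd45a, a stress-induced gene that the cell cycle inhibitor list also holds, changed by -2.02 (SE 0.20).

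**Figure D5:**
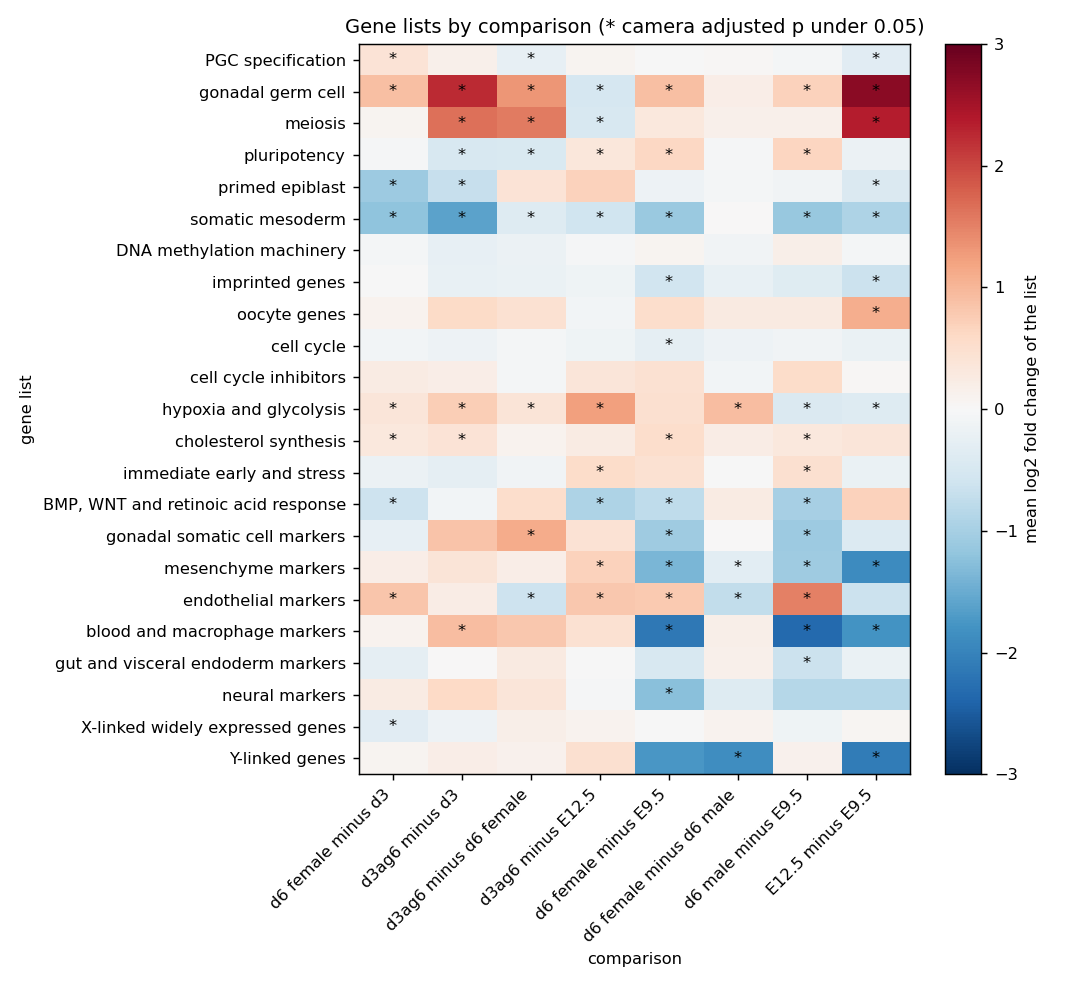
Mean log2 fold change of each of 23 gene lists (y axis) in each of 8 comparisons (x axis) as a colour scale, with a star where camera's adjusted p was under 0.05. The gonadal germ cell list averages 2.231 for d3ag6 minus d3 and 2.711 for E12.5 minus E9.5.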

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

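The test that counts gonadal somatic cell markers was chosen only after the result was seen, and the further macrophage list was drawn up after the pattern it tests was seen and before its own values were. The change from d6 female to d3ag6 PGCLCs (the culture step) was set against the change from E9.5 to E12.5 PGCs (the embryonic step), and the difference was tested as an interaction in limma. It was called for 773 genes, 441 with the higher change in culture and 332 with the lower. With the values as deposited these were 591 and 215, as the median difference over all genes went from -0.064 to 0.09. The count fell without any 1 array of d6 female, d3ag6 or E12.5. The array code differs between the groups of the embryonic step and not of the culture step, so that a shift between codes enters each of these differences. The groups of the culture step also differ by 3 days. The balance turned without E9.5 replicate 1, with 313 higher and 335 lower.

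Gonadal germ cell genes had a mean change of 1.321 in culture and 2.711 in the embryo, a difference of -1.39 (camera adjusted p = 6.4e-08; adjusted p = 0.18 with an estimated correlation). Dazl differed by -5.20 (SE 0.86, adjusted p = 0.0111). Meiosis genes, at 1.57 and 2.359, differed by -0.789 (adjusted p = 0.00269; adjusted p = 0.346 with an estimated correlation) and oocyte genes, at 0.465 and 1.091, by -0.626 (adjusted p = 0.0462; adjusted p = 0.18 with an estimated correlation). The oocyte call was lost without d6 female replicate 1 (-0.543), d3ag6 replicate 1 (-0.571), E12.5 replicate 2 (-0.561) or E9.5 replicate 2 (-0.543).

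For 6 other lists the mean was below 0 in the embryonic step and above 0 in the culture step. Taken by itself, the culture step was not called for mesenchyme, blood, primed epiblast and Y-linked genes, nor the embryonic step for gonadal somatic markers, whose median there was 0.038. Mesenchyme markers, at 0.192 in culture and -1.889 in the embryo, differed by 2.081 (adjusted p = 1.89e-07; adjusted p = 0.18 with an estimated correlation), and gonadal somatic cell markers, at 1.106 and -0.402, by 1.508 (adjusted p = 0.000449; adjusted p = 0.18 with an estimated correlation). Blood and macrophage markers differed by 2.616 (adjusted p = 5.87e-07; adjusted p = 0.18 with an estimated correlation), with a mean of 0.814 in culture and -1.802 in the embryo. The members called were not the same: Lyz2 and Tyrobp rose in culture, while 4 red cell genes fell and 1 gene rose in the embryo. Hypoxia and glycolysis genes, at 0.38 and -0.386, differed by 0.765 (adjusted p = 7.82e-05; adjusted p = 0.3 with an estimated correlation) and primed epiblast genes, at 0.407 and -0.442, by 0.849 (adjusted p = 0.00329; adjusted p = 0.186 with an estimated correlation), or by 0.52 (adjusted p = 0.043) without E9.5 replicate 1. Y-linked genes, at 0.119 and -2.102, differed by 2.221 (adjusted p = 0.0328; adjusted p = 0.18 with an estimated correlation), Kdm5d by 6.77 (SE 0.91, adjusted p = 0.00483) and Eif2s3y by 5.92 (SE 0.74, adjusted p = 0.00356). Here only E9.5 cells are not labelled female, so sex may be the cause. The Y-linked call was lost without d6 female replicate 2 (2.203), d3ag6 replicate 1 (2.117), E9.5 replicate 1 (2.108) or E9.5 replicate 2 (2.333).

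Of single genes, the change was higher in culture for Zfp503 (5.80, SE 0.92, adjusted p = 0.00952), Gad1 (5.64, SE 0.84, adjusted p = 0.00723), Hba-x (5.57, SE 0.55, adjusted p = 0.00224, at -0.62 in culture and -6.18 in the embryo) and Akr1cl (3.43, SE 0.48, adjusted p = 0.00572). Bcl3 (-4.89, SE 0.47, adjusted p = 0.00224) and Naprt (-2.04, SE 0.24, adjusted p = 0.00308) had the lower change in culture. Lyz1 (8.24, SE 1.36, adjusted p = 0.0111) lost its call without E12.5 replicate 2 (7.47). Ctss (9.67, SE 1.94, adjusted p = 0.0231) lost it without any 1 of the arrays of d6 female and d3ag6 or E12.5 replicate 1 (8.53 to 10.07). Dhrs3 (4.66, SE 0.98, adjusted p = 0.0275) lost it without any 1 of the 6 arrays of d6 female, d3ag6 and E12.5 (4.23 to 5.08). With values below 4.81 set to it, the difference was 0.88 for Dhrs3, 5.00 for Ctss, 4.80 for Lyz1, 2.82 for Gad1, 3.38 for Zfp503, 3.07 for Kdm5d and 3.55 for Eif2s3y, so for Dhrs3 most lies below it. Of the 12 genes, 9 were called without each array, as were 7 of the 9 lists.

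Lyz1, Lyz2, Ctss and Tyrobp, genes known from macrophages, were higher in d3ag6 than in d6 female PGCLCs. A candidate source is macrophages sorted together with the d3ag6 cells, but of a further list of 30 macrophage genes, of which 26 were tested, limma called 1 higher, C1qc (4.65, SE 0.54, adjusted p = 0.00246; named after its values were seen), and the median change was 0.098 (camera p = 0.543; p = 0.675 with an estimated correlation). This stays open, because 21 of the 26 genes exceeded 4.81 in d6 female cells, where a small share of other cells could be hidden: the most abundant were Ctsz (11.35 in d3ag6, 12.13 in d6 female), Fcgr1 (11.75 and 11.84), Apoe (10.03 and 10.96) and Lgmn (10.02 and 10.48). Gonadal somatic cells of all kinds sorted together with the d3ag6 cells may also be a source, with 3 of 14 markers called higher, which leaves this open too. How far reporter sorting removed either kind of cell was not tested, nor was expression by the germ cells themselves after contact with somatic cells.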

How the results depend on the processing

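Of the settings here, the fit of the 8 arrays coded EA1013 and the array code as a block were tests chosen after the data were seen. With a call that also needs a 2-fold change, the counts were 905 (d3ag6 minus d3), 778 (d3ag6 minus E12.5), 1142 (d6 female minus E9.5) and 1849 (E12.5 minus E9.5), fewer by construction. Without the filter on dim genes they were 313 (d6 female minus d3), 419 (d3ag6 minus d6 female), 775 (d3ag6 minus E12.5), 38 (d6 female minus d6 male) and 459 (difference of steps). Between the steps r was then 0.289, and 0.479 with the stricter filter. With the mean of all probe sets of a gene the counts were 338 (d6 female minus d3) and 796 (d3ag6 minus E12.5). In that setting 3 named genes turned: Ccnd3 to 0.178 (d3ag6 minus d6 female), Setdb1 to 0.125 (d3ag6 minus E12.5) and Taf1 to -0.199 (d6 female minus d6 male); the cause was not tested. With only the arrays compared, and so fewer residual degrees of freedom, the counts were 148 (d6 female minus d3), 765 (d3ag6 minus d3), 569 (d3ag6 minus d6 female), 560 (d6 female minus E9.5), 2 (d6 female minus d6 male) and 291 (d6 male minus E9.5). Leaving out 1 array gave ranges of 112 to 461 (d6 female minus d3), 588 to 955 (d3ag6 minus d3), 193 to 356 (d3ag6 minus d6 female), 363 to 573 (d3ag6 minus E12.5), 743 to 1353 (d6 female minus E9.5), 12 to 239 (d6 female minus d6 male), 849 to 1105 (d6 male minus E9.5), 1387 to 2541 (E12.5 minus E9.5) and 268 to 789 (difference of steps). For X minus autosomes in d3ag6 minus d3 the range was -0.188 to -0.082. With the array code as a block d6 male minus E9.5 gave 2004. With the EA1013 arrays alone the counts were 684 (d6 female minus d3), 1810 (d3ag6 minus d3), 1242 (d3ag6 minus d6 female) and 1555 (d3ag6 minus E12.5).

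Of 73 called list tests, 66 could be tested with the stricter filter, of which 48 kept the call and 18 lost it, and 71 with the mean of probe sets, of which 65 kept it and 6 lost it. The values as deposited kept 63 and lost 10, only the arrays compared kept 68 and lost 5, and no filter kept 70 and lost 3. Leaving out 1 array kept 244 calls and lost 48. No called list had the opposite sign in the values as deposited. For named genes, leaving out those arrays in turn gave 2180 tests, of which 1503 kept the call and 677 lost it. With only the arrays compared 178 calls of named genes were lost, without the filter 99, with the mean of probe sets 78 of 508 tested, with the values as deposited 18 and with eBayes trend and robust 7. Replicate numbers were not taken to pair the samples coded EA1013: same-numbered arrays correlated at 0.179, 0.198 and 0.206 among d6 female, d3ag6 and E12.5, but at -0.252, -0.239 and -0.15 in the pairs with d3. E9.5 and d6 male, whose equal numbers share a code, had 0.547, and the code as a block stands for that pairing. With the replicate block the counts were 547 (d6 female minus d3), 1541 (d3ag6 minus d3), 950 (d3ag6 minus d6 female), 1294 (d3ag6 minus E12.5), 2058 (d6 female minus E9.5), 225 (d6 female minus d6 male), 1496 (d6 male minus E9.5), 3414 (E12.5 minus E9.5) and 842 (difference of steps). It kept 528 calls of named genes and lost 17, and kept 70 of lists and lost 3: pluripotency in d3ag6 minus d3 (adjusted p = 0.062), and primed epiblast (adjusted p = 0.0701) and Y-linked genes (adjusted p = 0.0508) in E12.5 minus E9.5. The pseudocounts planned for a linear table were not run, since the table was on a log scale, and dim genes, amplified from little RNA, limit what the arrays resolve.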

Other observations

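The tests of X-linked gene dosage, of chromosome 16 and of d3 replicate 1 alone were chosen only after the results were seen. Imprinted genes were lower than at E9.5 in E12.5 PGCs and in d6 female PGCLCs, where group and array code cannot be told apart. At E12.5, 14 of 36 fell, 3 rose and 19 did not pass over all genes tested, with 14 down and 4 up adjusted over the list alone (median -0.318, camera adjusted p = 0.0145; adjusted p = 0.386 with an estimated correlation). In d6 female PGCLCs 10 fell, 2 rose and 24 did not pass, with 12 down and 2 up adjusted over the list alone (median -0.194, adjusted p = 0.00721; adjusted p = 0.385 with an estimated correlation). Without E9.5 replicate 1 the calls were lost (adjusted p = 0.0791 and 0.0707), and the E12.5 call was also lost with the mean of all probe sets of a gene (adjusted p = 0.0564). In d6 male PGCLCs against E9.5, where the codes are balanced, the list was not called (median -0.248, adjusted p = 0.0682), with 2 lower, 2 higher and 32 not called, and the same numbers adjusted over the list alone. Mesenchyme and blood and macrophage markers were lower in the same comparisons, by medians of -1.597 and -0.574 at E12.5 and of -1.004 and -0.313 in d6 female cells. Grb10, a growth inhibitor that is imprinted, changed by -3.77 (SE 0.31) at E12.5 and by -4.40 (SE 0.31) in d6 female cells. Between d3ag6 and E12.5 cells the list was not called (median 0.022, mean -0.137, adjusted p = 0.658), with 7 lower, 3 higher and 26 not called, and 7 down and 5 up adjusted over the list alone.

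Cholesterol synthesis genes were higher in d6 female PGCLCs than in E9.5 PGCs, with 3 of 19 up, 16 not called and 6 up adjusted over the list alone (median 0.619, adjusted p = 0.00597; adjusted p = 0.385 with an estimated correlation). The list was also called in d6 female minus d3 (median 0.293, adjusted p = 0.045; adjusted p = 0.522 with an estimated correlation). There limma called 0 members, over all genes tested or adjusted over the list alone, with 4 at an unadjusted p under 0.05. That call was lost without d3 replicate 2 (adjusted p = 0.555) or d6 female replicate 2 (adjusted p = 0.262), with the stricter filter (adjusted p = 0.0697) or with the mean of all probe sets (adjusted p = 0.0567). It was called in d3ag6 minus d3 with 3 up, 16 not called and 5 up adjusted over the list alone (median 0.335, adjusted p = 0.0297; adjusted p = 0.49 with an estimated correlation), and lost without d3 replicate 2 (adjusted p = 0.215), with the stricter filter (adjusted p = 0.111) or with the values as deposited (adjusted p = 0.0519). It was called in d6 male minus E9.5 with 1 up, 18 not called and 1 up adjusted over the list alone (median 0.202, adjusted p = 0.0428; adjusted p = 0.519 with an estimated correlation), and lost without E9.5 replicate 2 (adjusted p = 0.167) or d6 male replicate 2 (adjusted p = 0.235), with the stricter filter (adjusted p = 0.0993) or with the mean of all probe sets (adjusted p = 0.0757).

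Of the 197 genes that differ between d6 female and d6 male PGCLCs, 185 were autosomal and 9 lay on chromosome 16 (6 lower and 3 higher in female cells), which argues against direct dosage of X-linked genes, or a higher dose of chromosome 16 in male cells, as the whole cause. A shift between the array codes is argued against for chromosome 16 genes as a set, since they exceeded other autosomal genes by 0.278 in d6 male minus E9.5, where the codes are balanced (0.255 to 0.301 without each array of these groups); an extra copy of chromosome 16 in male cells may raise them, a hypothesis that was not tested on DNA. For the called genes a shift between the codes stays open: of the autosomal ones 64.3% (119; exact 95% interval 57 to 71.2%) had the same sign in E12.5 minus E9.5, the same contrast of codes on other arrays, against 59.1% of all autosomal genes, which that interval holds. Direct X dosage would raise X-linked genes in female cells, unlike the 4 of 8 that were lower, a sign kept without each array. They were picked by that sign, which a code shift could set, so it decides nothing. Dosage stays open for the 4 higher (odds ratio among genes called higher 0.93, 95% interval 0.25 to 2.45, Fisher's exact test p = 1). Indirect effects of X dosage, of chromosome 16 or of sex were not tested, nor were other differences between the cell lines. The count of 197 fell without either d6 female array or d6 male replicate 2.

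The lower X-linked genes at d6 than at d3 in female PGCLCs were not explained by their expression level, since of 10000 sets of autosomal genes matched on mean expression 0 had a median at or below that of X-linked genes (-0.209), and the lowest was -0.066. Nor did d3 replicate 1 alone carry the difference, which was -0.168 without it. Neither test bears on X inactivation, or on the loss of an X chromosome from some cells in culture, which may both lower X-linked genes and were not tested. Xist was not called (-0.47, adjusted p = 0.477).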
